A study of Caulobacter vibrioides CB15 with 23 samples.

How the data were processed

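Hi-C maps physical contact between parts of a chromosome by crosslinking, restriction digestion, ligation and sequencing. Per the labels, BglII was used for 18 libraries and NcoI for 3, and cells were swarmers or cells grown on from swarmers, while RNA came from mixed populations. The submitters' processing notes name Bowtie 0.12.7 and bedtools without saying what each did. The balancing method is not given in the sources used here. The deposited Hi-C values are contact fractions for 405 bins of 10 kb, given to 4 decimals, with each row summing to about 1. The diagonal and neighbouring bins are 0. Pairs of bins further apart were listed at 0 in 0.00737% to 4.76% of cells, depending on the library. Counts cannot be had from these fractions, so the Hi-C depth is unknown and no counting error is given. The deposited RNA values are coverage per base, a signal without strand or scaling, per the files. Isolated reads were 40 bases long, which gives the reads per library by division of total coverage. Coordinates are those of the NA1000 chromosome in the RNA files, and bin 1 was taken to start at its first base.

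The insulation score of a bin was log2 of the mean contact between the 5 bins before it and the 5 bins after it, minus the chromosome's median. Lower values mean less contact across the bin. Scores were compared per bin with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment, threshold 0.05). The fit of the 11 van-strain libraries had 3 residual degrees of freedom, from 3 duplicated groups, so single libraries were assumed to vary like these. A second fit took 2 starved, 1 chloramphenicol and 11 van-strain libraries as 3 groups, and strain differences away from the insertion thus count as spread. The single chloramphenicol library was assumed to vary like the van and starved libraries. Labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries. On simulated scores with the spread of the duplicated groups, the starved comparison called 12, 20 and 20 of 20 bins shifted by 0.25, 0.5 and 1 (log2) and 1 of 324 unshifted bins, among 384 bins. The full-length comparison called 2, 9 and 20 of 20 and 0 of 345, among 405 bins. The simulated noise was independent between neighbouring bins and of the same size in all bins. Real squares overlap and the real spread differs between bins, so these rates need not hold for the data.

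Tests, samples, alternatives and the rule for named regions were fixed before the data were examined. Several plans could not be followed, because no annotation of this build was at hand and the gene table given is of the CB15 assembly, from which only the coding length of rsaA was taken. The van locus was therefore located from the data, as the bin of the largest mean fall from promoterless to full length. Of the 10 other libraries of van strains, 5 had their own largest fall from promoterless there or in the next bin, the 2 full-length ones included. Native rsaA could not be placed, so its insulation, its contact with the van bin, the gene lists, rRNA bins and named genes were not run. Only the insertion site with 10 bins each side was left out of the bin tests, a choice made after the data were seen. The exact tests of starved against van-strain contact range and inter-arm contact, and the adjustment over 4 measures, were also added then. RNA was compared in 1 kb windows in place of genes, scaled to a mean of 100 per base, with a pseudocount of 1, a minimum scaled mean of 10 and a 4-fold limit. Fold changes are on the scale of value plus pseudocount.

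Regions named are the insertion site, the 10 changed bins of largest absolute difference per bin test, the 10 lowest boundaries of the van-strain mean, and the 10 windows of largest rise and fall in RNA, of which a selection is described. Each changed bin of the starved test is given with the 500 bp stretch of highest median coverage, in either RNA library, within 1 bin. Relations across bins were Spearman correlations with 2-sided p-values from all 405 rotations of the RNA profile. Boundaries were local minima with a prominence of at least 0.2. Shares of boundaries near the 10% of bins with the highest coverage were tested 1-sided over rotations. Transcribed length was tested by exact permutation of pairings. Contact range was the share of contact at 20 to 100 kb among that at 20 to 1000 kb. Inter-arm contact was log2 of mean contact within 3 bins of the mirror axis over contact at the same separations off it, for pairs over 300 kb apart. NcoI and BglII libraries were not compared. Alternatives were squares of 3 and 10 bins, the mean of log2 contacts, rebalanced contacts, the replicate block, each replicate left out, other controls, thresholds, axes, bands, prominences and RNA scalings. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.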

Results

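Chromosome conformation was measured by Hi-C in 21 libraries of Caulobacter crescentus NA1000 (also called CB15N), a bacterium whose newborn motile swarmer cells carry 1 unreplicated circular chromosome and can be isolated by density gradient. Of these, 11 libraries came from swarmers of 8 strains in the rich medium PYE. Each strain lacked native rsaA, the gene of the surface-layer protein, and carried an rsaA construct at the van locus. The other BglII libraries were 2 of wild-type swarmers starved in M2 salts for 90 min, 1 of wild-type swarmers given 50 µg/ml chloramphenicol, an inhibitor of translation, for 30 min, and 4 taken after IPTG was withdrawn from a strain whose dnaA, the replication initiator gene, was under a lac promoter. In the latter strain swarmers were isolated at 90 min and then left to elongate. A further 3 libraries, cut with NcoI, followed xylose-driven expression of the CtrA variant D51E. Full length, ATG to TAA, antiterminator and starved had 2 libraries each, and every other group had 1. RNA coverage was given for 2 libraries of unsynchronised wild-type cells, with about 5.17e+07 and 5.36e+07 reads of 40 bases for those labelled M2 and PYE. The depth of the Hi-C libraries is unknown, because the files hold fractions. Untreated wild-type Hi-C was not analysed here.

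The first comparison asked whether moving a highly transcribed gene to a new place makes a domain boundary there. With full-length rsaA at the van locus, insulation at positions 2610001 to 2620000 was -1.28 ± 0.09 (SD, n = 2), so contact across this bin was 41.1% of the chromosome's median. In the promoterless strain it was -0.11, or 92.7% of the median. The difference was -1.17 (SE 0.15, limma adjusted p = 0.0283 over all bins), a 2.25-fold lower contact in the mean, with -1.23 and -1.11 in the single full-length libraries. Insulation fell in 2 adjacent bins, the second being 2620001 to 2630000. The site was itself placed at the bin of the largest fall between these strains, so its position is not independent of this comparison. Adjusted over the list alone, of the site and 5 bins each side, 6 of 11 bins passed. The call was lost when either ATG to TAA library was left out, which changed the spread estimate and not the difference. With squares of 10 bins the call was also lost, and there the difference itself shrank to -0.93.

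The loss of contact reached over 100 kb. Between bins on opposite sides of the site, contact in the full-length strain relative to promoterless was -1.17 ± 0.14 (log2, SD, n = 2) at separations of 20 to 50 kb. It was -1.06 ± 0.11 at 60 to 100 kb, -0.65 ± 0.07 at 110 to 200 kb and -0.17 ± 0.10 at 210 to 400 kb. At 410 to 600 kb it was 99.8% of the promoterless level. Contact between bins on the same side of the site differed by 0.04 ± 0.04 at 20 to 50 kb apart and was higher by 0.127 ± 0.035 at 60 to 100 kb. At 60 to 100 kb every other strain was also above promoterless, by 0.056 (terminator at 1060 bp) to 0.173 (terminator at 60 bp). This same-side rise was thus not particular to full length, and all strains were set against the same promoterless library. The spreads are of the full-length libraries only, as promoterless had 1 library.

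**Figure D1:**
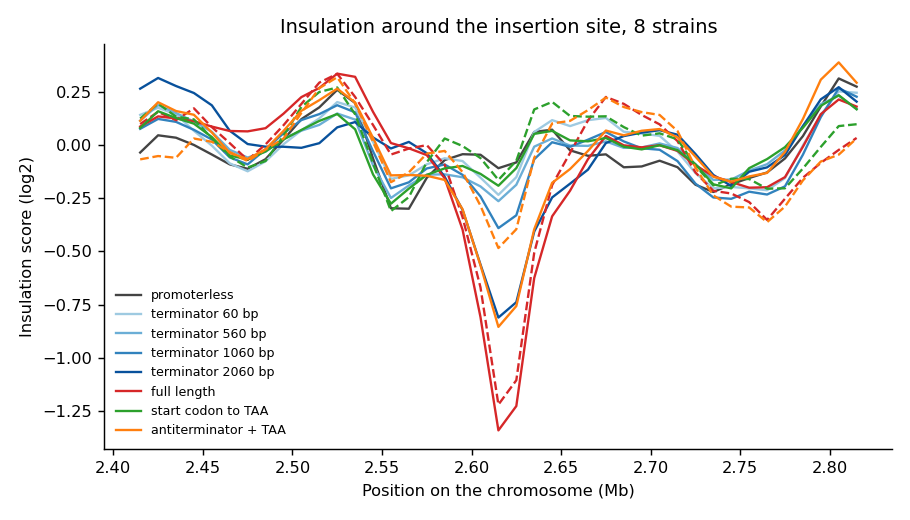
Insulation score (log2, vertical axis) against position (Mb, horizontal axis) for the 11 libraries of 8 strains, with dashed lines for replicate 2. The full-length libraries reach -1.34 and -1.22 at the site, and promoterless stays at -0.11.

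The next comparison asked whether the length of the transcript matters. Terminators placed 60, 560, 1060 and 2060 bp after the transcription start gave insulation of -0.23, -0.26, -0.39 and -0.81 at the site. Promoterless, taken as length 0, gave -0.11, and the full-length libraries, placed at the coding length of rsaA of 3081 bp in the CB15 annotation, gave -1.34 and -1.22. RNA of the van strains was not among the samples, so transcript length and level were not checked. Insulation fell with the transcribed length that the constructs allow, with Spearman's rho of -0.991 (2-sided exact permutation p = 0.000794, n = 7). Pearson's r was -0.987 (exact permutation p = 0.000397). Adjusted over the 2 coefficients, both exact p-values were 0.000794. Without the lengths farthest from the median, which are the full-length libraries, r was -0.973 (exact permutation p = 0.00833, n = 5). Without the replicate 2 full-length library, which belongs to a second set of libraries with another source name in the labels, rho was -1 (exact permutation p = 0.00278, n = 6). The second set holds only 1 library of this series, so it gives no value of its own. The site was chosen as the largest fall between promoterless and full length, the ends of this series, so the p-values above are not independent of that choice. Among the 4 terminator libraries, which had no part in it, rho was -1 (exact permutation p = 0.0833, the smallest that n = 4 allows).

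Each terminator strain and promoterless had 1 library, so their p-values assume the spread of the 3 duplicated van-strain groups. The strain with a terminator at 60 bp lay above full length by 1.05 (SE 0.15, limma adjusted p = 0.0430), a call lost with squares of 3 or 10 bins or without either ATG to TAA library. For 560 bp the difference was 1.02 (adjusted p = 0.0538), for 1060 bp 0.89 (adjusted p = 0.142) and for 2060 bp 0.47 (adjusted p = 0.978). Against promoterless, which sets 1 library against 1, the terminator at 2060 bp differed by -0.70, which no replicate tests.

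**Figure D2:**
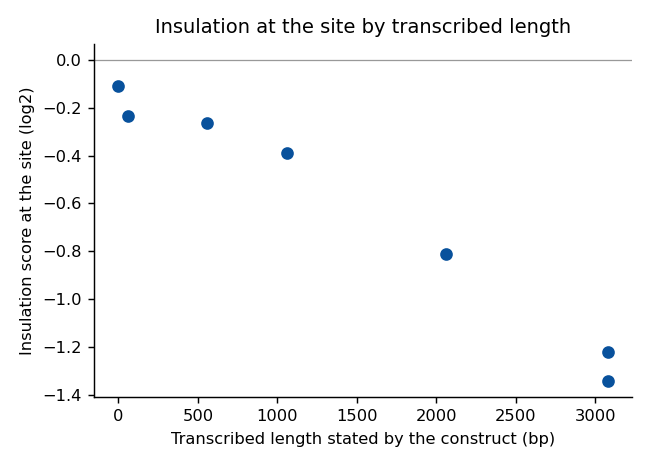
Insulation score at the site (log2, vertical axis) against the transcribed length that each construct allows (bp, horizontal axis), 1 point per library, 7 libraries. Scores go from -0.11 at length 0 to -1.34 and -1.22 at 3081 bp.

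A pair of further constructs kept the promoter and the length of the gene and lost the start codon. When the start codon was replaced by the stop codon TAA, insulation was -0.18 ± 0.02 (SD, n = 2), or 88.4% of median contact. This was 1.10 higher than in the full-length strain (SE 0.12, limma adjusted p = 0.00803) and higher within both replicate numbers, by 1.15 and 1.06. The site was chosen as the largest fall from promoterless to full length. P-values against full length, here and for the terminators above, are thus not independent of that choice. The interval of the difference from promoterless, -0.07, ran from -0.42 to 0.28, so the ATG to TAA strain and the strain without promoter could not be told apart. This call, too, was lost without either ATG to TAA library (adjusted p = 0.137 and 0.162).

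Adding an antiterminator to the start-codon mutant, which lets RNA polymerase read through terminators, gave -0.67 ± 0.26 (SD, n = 2), or 62.9% of median contact. The difference from ATG to TAA was -0.49 (SE 0.12, 95% interval -0.78 to -0.21), lower in both replicate numbers, by -0.66 and -0.32. Over all bins it did not pass in limma (adjusted p = 0.966, no bin called, 5 bins at an unadjusted p under 0.05). Adjusted over the list alone it passed (limma adjusted p = 0.0262, 2 of 11 bins). Without antiterminator replicate 2 the difference was -0.68, and without replicate 1 it was -0.31. In replicate 1 the site had the largest fall from promoterless of all bins, by -0.75. In replicate 2 it ranked 12, with -0.38, and the largest fall was -0.59 at 30001 to 40000. The change at the site in replicate 2 was thus no larger than at some bins away from it.

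RNA in the library labelled M2 was concentrated in few places. The top 1% of bases held 66.2% of its coverage, against 35.8% in the library labelled PYE, and its median coverage was 6.07% of the mean, against 21.5%. Of 2981 windows of 1 kb with enough coverage, 9.09% were at least 4-fold higher and 39.8% at least 4-fold lower in the library labelled M2 when scaled to total coverage. The median difference was then -1.45 (log2), and scaled to this median the shares were 20.4% and 18.95%. There was 1 library per condition, so these are differences between libraries with no replicate check. The labels contradict each other on the medium: title and characteristics give one, and the treatment protocol gives the other for each library.

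The window of largest rise in the library labelled M2 was 3328001 to 3329000, with mean coverage of 207211 against 447 in the library labelled PYE (log2 difference 8.90 after scaling to total coverage). The window 3508001 to 3509000 had 173512 against 483 (8.53), and 2521001 to 2522000 had 35421 against 174.4 (7.68). At 1180001 to 1181000 the difference was 7.08, and at 2353001 to 2354000 it was 7.38. The 10 windows of largest fall lay in 3 stretches. Within 1433001 to 1437000 coverage was highest in the last window, at 15987 in the library labelled PYE and 178.1 in that labelled M2 (-6.39). Within 3257001 to 3261000 the last window differed by -6.80, and within 3626001 to 3629000 it differed by -6.57. No annotation of this build was used, so the windows carry no gene names.

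The starvation Hi-C asked whether domains move when transcription changes. Starved swarmers had their lowest insulation at 1170001 to 1180000, with -1.06 ± 0.04 (SD, n = 2) against -0.29 ± 0.08 (SD, n = 11) in the van strains, a difference of -0.77 (SE 0.05, limma adjusted p = 9.46e-08). The stretch of highest coverage within 1 bin of it, 1159751 to 1160250, was lower in the library labelled M2, with median coverage of 23323 against 58993.5 in that labelled PYE. The starved cells carry native rsaA and all 11 van-strain libraries lack it, and its position was not known here. In the 4 libraries after IPTG withdrawal, which were not starved and carry native rsaA, insulation was -0.43 to -0.36 at 1170001 to 1180000 and -0.30 to -0.18 at 1180001 to 1190000. At the bin before, 1160001 to 1170000, they were at -0.63 to -0.54, close to the starved libraries at -0.67 and -0.63. The next bin, 1180001 to 1190000, fell by 0.70 (SE 0.05), and RNA at 1180201 to 1180700 within it was higher, at 44852 against 333.5. Insulation also fell at 3010001 to 3020000 and 3020001 to 3030000, by 0.62 in each, beside RNA at 3019001 to 3019500 of 20970 against 221.5. The starved libraries lay further apart there than at 1170001 to 1180000, with SDs of 0.32 and 0.21 (n = 2). Insulation fell by 0.52 and 0.49 in the bins from 1490001 to 1510000, beside RNA at 1503201 to 1503700 of 46297.5 against 417. The bin 2500001 to 2510000 fell by 0.57, and the stretch of highest coverage near it, at 2493601 to 2494100, had 89 against 594.5.

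Other boundaries became shallower. Insulation rose by 0.46 at 1440001 to 1450000. RNA beside it went both ways. The stretch of highest coverage, 1430201 to 1430700, was higher in the library labelled M2 by 7.32 (log2, scaled to total coverage), while 1433001 to 1437000 was lower. It rose by 0.48 at 2860001 to 2870000, where RNA at 2867701 to 2868200 differed by -5.41. It rose by 0.49 at 3790001 to 3800000, where RNA at 3797901 to 3798400 differed by -5.70. Among the 10 named bins, the stretch of highest coverage went against the direction of the insulation change in 7, which share 5 stretches. It went with that direction in 3, among them 2500001 to 2510000. That bin is at the edge of the left-out bins, where a deeper boundary lay beside RNA that was higher in the library labelled M2. These counts change places if the RNA libraries are named by the treatment protocol. In all, 47.4% of the bins tested changed in limma (adjusted p under 0.05), 27.1% lower and 20.3% higher, in 42 runs of neighbouring bins. The control was the van strains, which differ from wild type at rsaA and van, and with the 2 full-length libraries as the control 3 bins passed. Without starved replicate 1 the share was 14.3%, and without all replicate 2 libraries it was 51.3%.

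**Figure D3:**
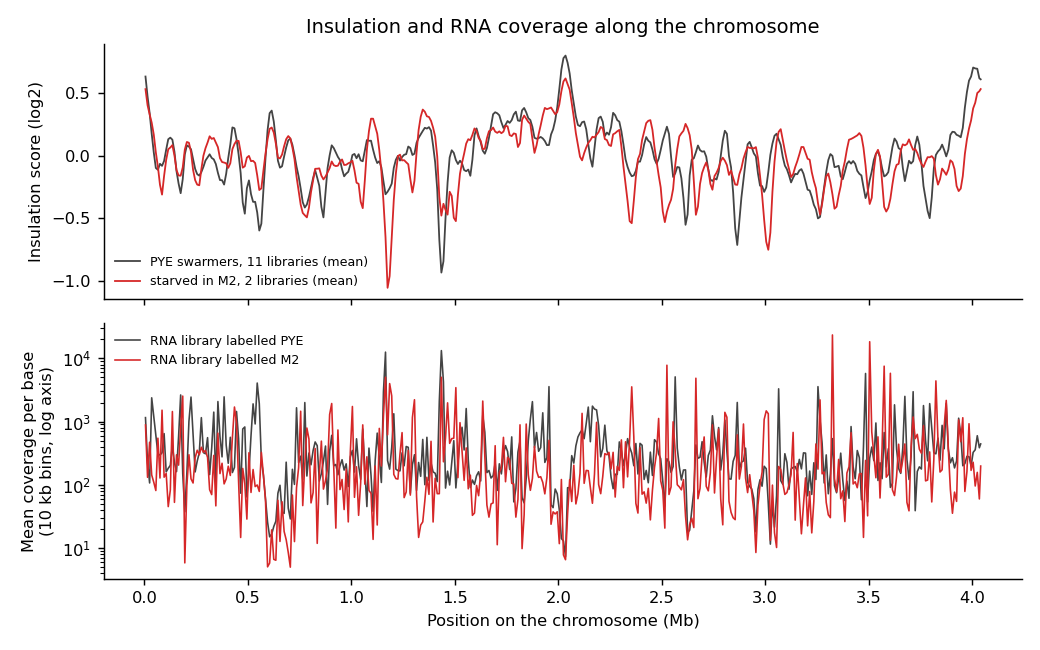
Top, insulation score (log2) along the chromosome (Mb) as the mean of 11 PYE libraries of van strains and of 2 starved libraries. Bottom, mean RNA coverage per base in 10 kb bins on a log axis. The lowest starved value is -1.06 at 1170001 to 1180000.

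Against the van-strain mean, the chloramphenicol library, of wild-type cells, had deeper boundaries at 2 places where starvation made them shallower, and shallower ones elsewhere. Insulation at 2860001 to 2870000 was -1.57 against -0.71 ± 0.20 (SD, n = 11), a difference of -0.86, and the lowest of the 11 was -1.07. Its neighbours on both sides fell by 0.65 and 0.49. At 3790001 to 3800000 insulation was -1.24 against -0.50 ± 0.18 (SD, n = 11), a difference of -0.74 with the lowest of the 11 at -0.85, and its neighbours fell by 0.50 and 0.45. The 4 libraries after IPTG withdrawal carry native rsaA and had no chloramphenicol. They were at -1.49 to -0.86 at 2860001 to 2870000 and at -1.37 to -0.44 at 3790001 to 3800000. The library at 90 min, when swarmers were isolated, was at -0.86 and -0.44 in these bins, nearer the van-strain mean than the chloramphenicol library. The lowest values came from later times, in cells left to elongate. At the latter bin the lowest was below the chloramphenicol library, so such depth was also seen without chloramphenicol, but not in the swarmers at 90 min. Other boundaries of the van strains were shallower in the chloramphenicol library than in the van-strain mean, without passing in limma: 1430001 to 1440000 at -0.44 against -0.93, 550001 to 560000 at -0.28 against -0.60, and 480001 to 490000 at -0.02 against -0.46. Starvation made these shallower too, with -0.48, -0.27 and -0.08. The library had 14 boundaries, against 23.7 ± 2.10 (SD, n = 11) per van-strain library. Insulation rose by 0.43 at 80001 to 90000 and at 3850001 to 3860000, and fell by 0.42 at 2040001 to 2050000 and at 4020001 to 4030000. In all, 15.6% of the bins tested passed in limma, or 60 bins, 40 lower and 20 higher. With 1 treated library the spread comes from the van and starved libraries, so these p-values rest on the assumption that it varies like them, and no replicate tests that. With the full-length libraries alone as control 5 bins passed, and without the replicate 2 libraries 29.7% did.

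Across the chromosome, low insulation went with RNA in starved cells when the RNA libraries are named by their titles. Spearman's rho across bins between starved insulation and coverage in the library labelled M2 was -0.336 (permutation p = 0.00247 over all rotations, the smallest they can give, adjusted 0.00412). The change in insulation on starvation went against the change in coverage, with rho of -0.353 (rotation permutation p = 0.00247, adjusted 0.00412), a sign that turns if the RNA libraries are named by the treatment protocol. That naming also gave -0.130 for starved cells (rotation permutation p = 0.175) and -0.165 for the van strains (rotation permutation p = 0.0444). For the van strains and the library labelled PYE, rho was -0.164 (rotation permutation p = 0.116, adjusted 0.116). The relations of starved cells and van strains were not tested against each other. Bins are not independent replicates, and these values describe 1 RNA library per condition. The adjustment is over 5 relations, the 2 boundary tests included.

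The mean profile of the van strains had 26 boundaries. The lowest lay at 1430001 to 1440000 (-0.93 ± 0.28, SD, n = 11), 2860001 to 2870000 (-0.71 ± 0.20), 550001 to 560000 (-0.60 ± 0.14), the insertion site (-0.55 ± 0.44) and 3250001 to 3260000 (-0.50 ± 0.03). Of the 25 away from the site, 15 lay within 1 bin of the 38 bins with the highest coverage in the library labelled PYE, or 60.0%, against 24.4% on average over rotations (permutation p = 0.00494, adjusted 0.00617). Starved cells had 24 boundaries, and 13 of 22 away from the site lay near bins of highest coverage in the library labelled M2, against 23.95% over rotations (permutation p = 0.00247, adjusted 0.00412). Within 1 bin, 9 of the 26 boundaries in PYE were also found in starved cells, and rotations gave 4.62 (permutation p = 0.0370). Between replicates, 16 of 24 starved, 15 of 22 ATG to TAA, 14 of 25 antiterminator and 12 of 21 full-length boundaries were shared.

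The time courses asked how the chromosome's contacts change in cells that elongate without dividing. After IPTG withdrawal, contact at 20 to 100 kb made up 38.9% of that at 20 to 1000 kb at 90 min, 48.7% at 150 min, 55.5% at 210 min and 59.1% at 270 min. The pooled SD of the 4 duplicated groups was 1.94. The treatment protocol of the library labelled 150 min adds up to a longer time. Contact between the arms, along an axis through the first base of the reference, went from 1.42 (log2) at 90 min to 0.89, 0.53 and 0.70, with a pooled SD of 0.12. The SD of insulation over bins went from 0.29 to 0.35, 0.40 and 0.38, with a pooled SD of 0.02.

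The CtrA series moved the same way. The share within 100 kb was 39.5%, 53.5% and 57.8% at 0, 2 and 3 h after xylose. Inter-arm contact was 1.72, 1.32 and 1.14, and the SD of insulation was 0.32, 0.37 and 0.39. With 1 library per time these are values without a test. With the axis placed where the score was highest in each library, the change in inter-arm contact was -0.36 after IPTG withdrawal and -0.32 after xylose, in place of -0.72 and -0.59. On that axis the values were 1.82, 1.80, 1.44 and 1.46 after IPTG withdrawal and 1.87, 1.88 and 1.55 after xylose, so the early fall was seen on the fixed axis only.

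**Figure D4:**
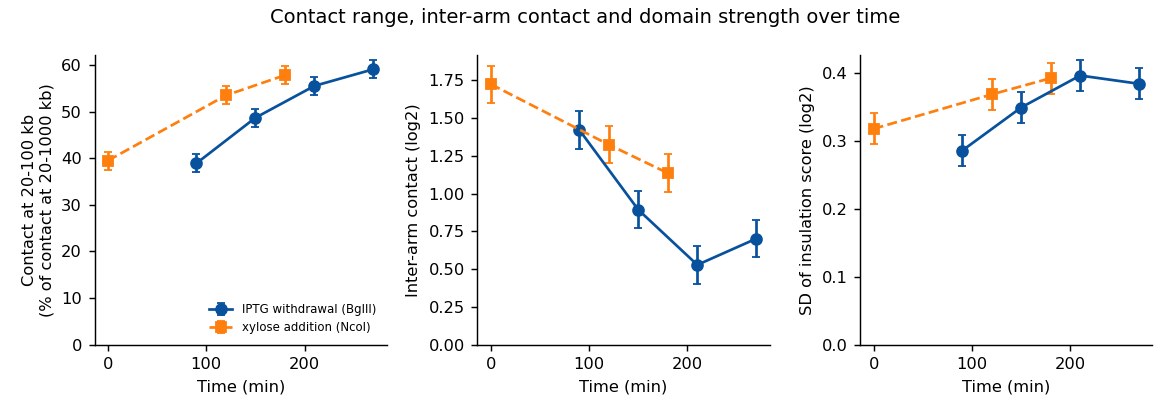
Contact within 100 kb (percent of contact at 20 to 1000 kb), inter-arm contact (log2) and SD of insulation over bins (log2) against time (min), 1 library per point. Bars are the pooled SD of 4 duplicated groups, all cut with BglII, so the NcoI points of the xylose series have no spread of their own. The share within 100 kb goes from 38.9% to 59.1% after IPTG withdrawal.

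In starved cells the share within 100 kb was 33.8% ± 3.27 (SD, n = 2) against 40.4% ± 1.58 (SD, n = 11) in the van strains (exact permutation p = 0.0128, the smallest that 78 splits allow, and 0.0513 adjusted over 4 measures). Inter-arm contact was 1.53 ± 0.13 against 1.52 ± 0.10 (exact permutation p = 0.974) on the fixed axis, and 1.54 ± 0.13 against 1.68 ± 0.10 (exact permutation p = 0.128) with the axis of highest score in each library. The chloramphenicol library had 33.5% within 100 kb.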

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

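Leaving out the replicate 2 libraries was chosen after seeing the data, as were leaving out no bins in the starved and chloramphenicol tests, the 2 farthest lengths left out, promoterless and full length left out of the length series, the replicate block for chloramphenicol, leaving out the bins around the highest PYE coverage, the 2 kb RNA stretch, and other squares for domain strength. The difference between full length and promoterless lay between -1.23 and -1.11 when single libraries were left out, that between ATG to TAA and full length between 1.04 and 1.16, and that between antiterminator and ATG to TAA between -0.68 and -0.31. With squares of 10 bins, full length minus promoterless was -0.93 (limma adjusted p = 0.0835, range over alternatives 0.00207 to 0.142), and ATG to TAA minus promoterless was 0.00010045. The relation with transcribed length kept its sign in all alternatives and its side of the threshold in all but that of the 4 terminator libraries (rho -1, exact permutation p = 0.0833), which is too few to pass. Starved bins were 0.781% of those tested with full-length controls, 28.4% at a threshold of 0.01, and 14.3% to 50.5% with single libraries left out (32.8% without starved replicate 2). Chloramphenicol bins were 28.6% with squares of 10 bins, 1.302% with full-length controls, 6.25% at a threshold of 0.01, and 29.7% without the replicate 2 libraries. The full-length control leaves few libraries for the spread, and 96 starved and 56 chloramphenicol bins had an unadjusted p under 0.05 there. RNA windows higher and lower in the library labelled M2 were 20.4% and 18.95% under median scaling, and 39.8% and 9.09% if named by the treatment protocol. That naming gave rho of -0.165 for the van strains (rotation permutation p = 0.0444), -0.130 for starved cells (p = 0.175) and 0.353 for the change. Boundaries numbered 10 and 13 (van strains, starved) at a prominence of 0.4, and 13 and 13 with squares of 10 bins. The rise in short-range share was 17.4 and 15.02 (IPTG, xylose) within 50 kb and 15.2 and 14.5 within 200 kb, and the inter-arm change was -0.36 and -0.32 on the best axis. Except where numbers of libraries or the measure itself changed, the cause was not tested. The replicate block, for numbers that the labels do not call a batch although replicate 2 libraries have another source name, called 49.5% of the bins tested for starvation and gave differences of -1.26, 1.10 and -0.49 for the 3 contrasts above, and the same calls for these. It added calls at the site against full length for antiterminator (limma adjusted p = 0.0453) and for terminators at 1060 bp (0.0132) and 560 bp (0.00503), and changed no other call at the site. Of the starved bins 14 were gained and 6 lost, and of chloramphenicol bins, now 24.2% of those tested, 33 were gained and none lost. Deviations correlated by 0.797 between antiterminator and full length, and by -0.042 to 0.199 in other pairs of groups. Analyses that need gene positions were not run. Unknown Hi-C depth leaves counting error unmeasured.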

Other observations

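The tests of swapped RNA labels, of a common pool of reads and of native rsaA, and the stretches of other lengths, were chosen after the results were seen. The prediction for a few biased bins was written before its value, but after the shared pattern had been explored. The rule by which reads shared between libraries would be kept or excluded was changed after its value was known. Stretches of coverage were also compared with insulation by length. For the van strains and the library labelled PYE, rho across bins was -0.242 with the highest median coverage over 100 bp (rotation permutation p = 0.00247, adjusted 0.00404 over 18 relations), -0.217 over 1000 bp (adjusted 0.0381) and -0.0775 over 8000 bp (adjusted 0.684). For starved cells and the library labelled M2 it was -0.319, -0.318 and -0.225, with -0.322 over 500 bp. No difference between lengths was tested.

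The mirror axis between the arms lay away from the first base of the reference in PYE libraries of the van strains, at -51.8 ± 19.9 kb (SD, n = 11), and at -12.5 ± 3.54 kb (SD, n = 2) in starved cells. Single van-strain libraries ranged from -85 to -20 kb, so some lay close to the starved ones. The axis was at -10.0 kb with chloramphenicol. After IPTG withdrawal it was at -80, -80, -70 and -75 kb at 90, 150, 210 and 270 min. After xylose it was at -50, -80 and -90 kb at 0, 2 and 3 h. The axis was chosen as the highest score in each library, and no test was planned.

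In starved cells insulation fell where RNA rose, by rho of -0.353. With the libraries that carry native rsaA, chloramphenicol and 90 min after IPTG withdrawal, as control, rho was -0.351 (rotation permutation p = 0.00247). The relation thus did not depend on knock-out controls. Both versions use the same starved libraries, whose insulation alone gave -0.336 with the library labelled M2, so a negative rho was likely with either control. Without the 10% of bins of largest RNA change rho was -0.253 (rotation permutation p = 0.00494), so a few extreme bins do not account for it. Swapped RNA labels stay open. Starved insulation followed the library labelled M2 more closely than that labelled PYE, by -0.206 (rotation permutation p = 0.00741), but van-strain insulation followed both alike (-0.165 and -0.164), and the test takes low insulation to go with transcription. A change of domains with transcription may account for the relation, as a hypothesis found and tested on the same data.

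The replicate 2 libraries of starved, ATG to TAA, antiterminator and full length shared a fine-scale pattern of contacts over 300 kb apart. Residuals from the local mean correlated by a median of 0.408 over their 6 pairs and 0.0197 over the other pairs of BglII libraries. Leaving out the 20 bins of largest shared deviation left 0.336, which argues against a bias of a few bins and is what reads shared between libraries would also give. A large common pool of reads would have drawn these libraries together at the insertion site, but their differences from full length there were 0.963, 1.00 and 1.81 times those among replicate 1 libraries. These are differences in contact as a fraction of the median, not in log2. Each ratio rests on a single bin and on single libraries, and that of 1.81 shows how far spread between replicates can move it. The ratios therefore cannot exclude a common pool. Shared reads and a preparation or processing particular to this set cannot be told apart, since the set differs from the rest in its source name and replicate number together. No biological explanation was tested.

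The 2 kb of highest median coverage in the library labelled PYE, extended while coverage stayed at 5000 or more, ran from 1159642 to 1162760, with median coverage of 42957, and 16860 in that labelled M2. Its 3119 bp are close to the 3081 bp coding length of rsaA, so it may be native rsaA. At its bin, 1160001 to 1170000, 4 of 5 unstarved BglII libraries with native rsaA lay below all 11 knock-out libraries, between -0.63 and -0.54 against -0.31 ± 0.04 (SD, n = 11), and with the starved libraries (-0.67 and -0.63) 6 of 7 did. The remaining one, chloramphenicol, was at -0.29, so the hypothesis cannot be told apart from other differences between these strains. At this bin the fall on starvation is thus confounded with the control genotype, while at 1170001 to 1180000 starved insulation of -1.06 lay below that of the unstarved libraries with native rsaA, at -0.43 to -0.28.

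The insulation profiles of ATG to TAA replicate 1 and the terminator at 560 bp correlated by 0.994, the highest of all pairs of BglII libraries, while their fine-scale residuals correlated by 0.0766.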
